A study of Mus musculus with 12 samples.

How the data were processed

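Total RNA of mouse cardiac stem cell cultures was sequenced, per the labels' protocols, after ribosomal RNA depletion, from 1 µg of RNA with an integrity number of at least 8, as paired reads of 100 bp. The submitters' processing notes name DESeq, without a version, and the genome build mm10. The aligner, the annotation used for counting and whether strand was used are not given in the sources used here.

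Per the file headers, the deposited tables hold a raw and a normalized column for each of 6 cultures, in 34174 genes, and a second table holds 4528 of these genes with the authors' fold. The column names match the culture numbers of the titles, 3 wild-type and 3 c-kitCre, and not single libraries, so a culture is the replicate. The raw values, treated as a deposited signal, are not whole numbers. Among 71743 values under 14, 17.9% were whole and 28.3% had a whole square (tolerance 0.002, where chance gives 0.4%). A geometric mean of 2 whole library counts always has a whole square, so most of these values did not have that form. How the 2 libraries of a culture were merged is therefore not known. The raw values were not tested as counts. The deposited normalized values are on a log2 scale. They equal the log2 of raw value times a scale factor per culture (0.825 to 1.52), raised to a common floor of 4.41 scaled reads, minus a constant per gene. This was worked out from the values (largest deviation 2.04e-06 over 8369 genes with raw values over 200). The authors' fold equals 2 to the power of the absolute difference of the mean normalized log2 values, with a positive sign where wild-type is higher. Both tables hold the same values for shared genes.

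Summed raw values ran from 22371439 to 35963488 per culture. The values merge 2 libraries, and no interval is given for single values. For the spread between cultures of one group alone, counting error was approximated by treating each raw value as the mean of 2 Poisson counts, which is an assumption. Of the gene IDs, 32874 matched GENCODE M21 (the mm10 assembly) and 1300 did not, and coordinates come from that annotation. No mitochondrial messenger RNA of the list fixed for them was in the table.

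The genotype test was run with limma 3.58.1 (R 4.3.3), two-sided, with eBayes and trend, on the deposited normalized log2 values with the constant per gene added back, 3 cultures against 3, without covariates (4 residual degrees of freedom). Genes with a mean under 1 scaled read, or at the floor in all 6 cultures, were left out (10023 of 34174). This filter was written beforehand for a test on linear values. Here it was applied to the scaled reads, while the test used log2 values. Adjusted p-values are Benjamini-Hochberg over the 24151 genes. Lists with at least 5 genes were tested with camera (preset correlation 0.01), adjusted over 28 lists. Kit also had an exact permutation test. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

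The tests were fixed before the data were examined, except that the plan for log2 values had no filter and took them as deposited. Without the filter, limma called 6892 genes. The gene lists and the named-gene rule were fixed beforehand. The rule names Kit, the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05 and no overlap of the groups, predicted and unnamed genes left out, and up to 4 members with the smallest p in each list. A gene that this rule names is not reported here. The planned comparison of single libraries and of cultures within a genotype needs values per library and was not analysed here.

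On data simulated for the genotype comparison with 24151 genes, the fit recovered 2% of 50 genes changed by 0.58 on the log2 scale, 16% at 1, 60% at 2 and 96% at 4, with 1 false call in 88, and a shifted list was called. Only 50 genes were changed at each size, with noise drawn independently for each gene. The real data had 8578 calls, which makes the adjusted threshold less strict, so these rates do not give the power of the real test. The simulated list had no correlation between its genes. Alternatives were other filters, other pseudocounts on scaled reads (0.1, 1 and 5), quantile normalization, 2 median centrings, scaling to the summed raw values, the culture number as a block, fry, camera with an estimated correlation, and leaving out each culture. For chromosomes, the medians of the log2 difference over 11804 protein-coding genes with a mean of at least 50 scaled reads were used, with 100000 permutations of chromosomes and 1000 shuffles of blocks of 20 neighbouring genes. Transcript GC content and length came from the longest GENCODE transcript of each gene.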

Results

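RNA was sequenced from mouse cardiac stem cell cultures, cells of the heart expanded on gelatin-coated dishes, of 2 genotypes: wild-type and c-kitCre, in which the Cre recombinase gene sits in the Kit locus. The labels number 3 cultures per genotype and give each of them 2 libraries, 12 libraries in all. The tables used here hold 1 value per culture and gene, so n = 3 cultures per group throughout. The labels do not say whether the numbered cultures came from separate animals, and p-values therefore measure the spread between these cultures. The authors' deposited comparison is named a clone analysis, and whether the cultures were clones of a common line is not stated. Summed raw values were 35043499, 32392712 and 34854988 for the cultures labelled wild-type and 35963488, 22371439 and 26546087 for those labelled c-kitCre, with means of 34097066 ± 1479021 and 28293671 ± 6962506 (SD, n = 3). Levels are given below as scaled reads, the raw value of a culture multiplied by the scale factor contained in the authors' normalized values. Coordinates are those of mouse build mm10.

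Kit, the receptor tyrosine kinase gene that carries Cre in the c-kitCre animals, was examined first. Kit (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722) stood at 3.38, 1.55 and 1.17 scaled reads in the cultures labelled wild-type and at 1732, 1738 and 1603 in those labelled c-kitCre. The means were 2.03 ± 1.18 and 1691 ± 76.4 scaled reads (SD, n = 3), so that the level in the cultures labelled wild-type was 0.120% of that in the other group, an 832-fold difference. The log2 difference on the floored normalized scale was 8.51 ± 0.24 (SE; limma, unadjusted p = 1.45e-08, adjusted p = 3.49e-05), and an exact two-sided permutation test of the culture values gave p = 0.1, the smallest that 3 cultures against 3 allow. An insertion of Cre into the Kit locus predicts no more Kit in the carriers than in wild-type cells, so this gene goes against the labels. The groups are therefore called the cultures labelled wild-type and the cultures labelled c-kitCre, and every direction below rests on those labels.

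The comparison of the genotypes asks how the RNA of c-kitCre cultures differs from that of wild-type cultures. The genes with the steepest rise in the cultures labelled c-kitCre included Lama4, a laminin chain of the basement membrane, from 8.00 ± 4.47 to 20288 ± 1704 scaled reads, and Cxcl12, a chemokine of stromal cells, from 4.85 ± 2.34 to 10661 ± 1547 (SD, n = 3). Grb10, an imprinted adaptor of insulin signalling, rose from 7.43 ± 1.92 to 8198 ± 617. Xist, the RNA that coats the inactive X chromosome, fell from 35379 ± 4291 to 48.4 ± 17.5. Msln, a surface protein of mesothelial cells, fell from 6950 ± 832 to 43.5 ± 22.8. Of 24151 genes tested, 8578 (35.5%) differed at an adjusted p under 0.05 in limma, 3909 higher and 4669 lower in the cultures labelled c-kitCre, and 6234 of them differed at least 2-fold (3059 higher, 3175 lower). Of those past the threshold, 499 were at least 16-fold higher and 154 at least 16-fold lower. The 3 values of one group lay wholly above or below those of the other for 11965 genes (49.5%), where chance gives 10%. The direction depended on scaling: median centring over all genes, which moved the median log2 difference from 0.04 to -0.31, gave 2833 higher and 8663 lower, and centring on genes with a mean of at least 50 scaled reads, chosen after the data were seen, moved it to 0.26 and gave 5624 higher and 3811 lower. Without wild-type culture 2 the count fell to 5712, and without wild-type culture 1 it rose to 9047.

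**Figure D1:**
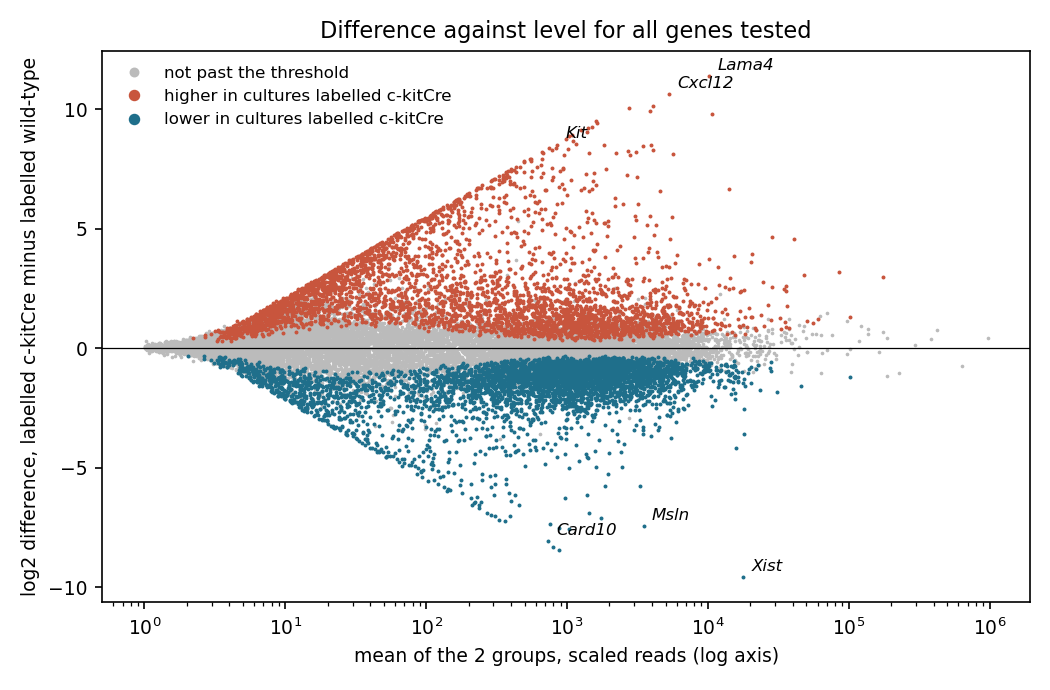
Log2 difference between the groups (labelled c-kitCre minus labelled wild-type, vertical axis) against the mean of both groups in scaled reads (horizontal log axis), 1 point per gene tested. Of 24151 genes, 3909 are coloured as higher and 4669 as lower in the cultures labelled c-kitCre at an adjusted p under 0.05; the slanted edges are set by the floor of the normalized values at 4.41 scaled reads.

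Among the other genes of the 12 largest rises, Adm, a vasodilator peptide induced by low oxygen, reached 5490 ± 2799 scaled reads, Tubb3, a neuronal beta-tubulin, 7783 ± 178, Thy1, a surface glycoprotein of fibroblasts and other cells, 3262 ± 248, and Sfrp1, a secreted Wnt inhibitor, 3021 ± 714 (SD, n = 3). Tmem45a reached 3208 ± 677, Fstl3, an activin-binding protein, 2826 ± 657, Aplp1, a relative of the amyloid precursor protein, 2517 ± 637 and Fbn2, a fibrillin of microfibrils, 2785 ± 643. The means of these 8 genes in the cultures labelled wild-type lay between 1.93 (Aplp1) and 7.90 (Tubb3). Nos2, the inducible nitric oxide synthase, rose from 67.6 ± 103 to 21375 ± 5277, where the starting mean rests on wild-type culture 1 and is 8.35 without it. Adjusted p-values of these 12 largest rises, Lama4, Cxcl12 and Grb10 included, ran from 1.99e-05 for Cxcl12 to 0.00158 for Nos2 (limma). Where a group lies near the floor, the log2 difference is limited by it, as for Lama4 (11.39 ± 0.37, SE) and Cxcl12 (10.62 ± 0.19). Group means under 10 scaled reads also lean on single cultures: for example, those of Tubb3, Fstl3, Nxf3, ERDR1, Eya1, Anpep, Pparg, Notum, Ifih1, Oas1a and Ddx3y moved by over 1.5 times with 1 culture left out.

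Beside Xist and Msln, the 12 largest falls included Card10, a scaffold of NF-kappaB signalling, from 1466 ± 272 to 5.14 ± 2.94 scaled reads and Atp2a3, a calcium pump of the endoplasmic reticulum, from 1757 ± 319 to 10.1 ± 4.13 (SD, n = 3). Nxf3, an X-linked RNA export factor, fell from 1763 ± 239 to 3.35 ± 3.15 and Eya1, a developmental transcriptional coactivator, from 577 ± 59.1 to 2.78 ± 2.29. Anxa8, an annexin, fell from 3459 ± 1666 to 23.5 ± 0.95, Ablim1 from 2042 ± 1320 to 8.15 ± 3.65, Cdh13, a cadherin without a transmembrane domain, from 1504 ± 762 to 9.02 ± 3.88, and Rab3b from 781 ± 655 to 3.91 ± 2.16, with large spreads in the cultures labelled wild-type (the mean of Rab3b is 402 without wild-type culture 1). ERDR1 fell from 1581 ± 689 to 1.65 ± 1.20, a value left uncertain because the gene has near-identical copies in the pairing region of X and Y. Adjusted p-values of these falls ran from 3.73e-05 for Xist to 0.000571 for Ablim1 (limma). Counting by strand is not stated, so reads shared by Xist and its antisense partner Tsix cannot be told apart. Tsix as counted measured 8.28 ± 2.10 and 8.64 ± 6.08 scaled reads in the cultures labelled wild-type and c-kitCre (SD, n = 3).

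**Figure D2:**
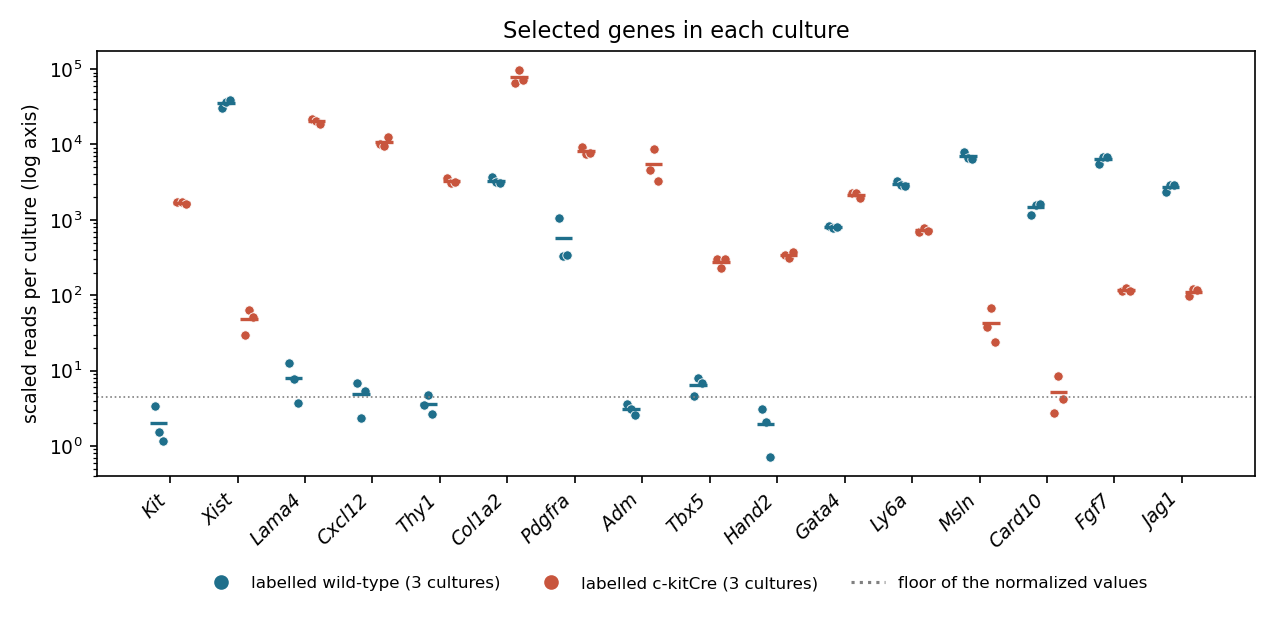
Scaled reads (vertical log axis) of 16 genes in each culture, 3 points per group, with a bar at the group mean; the dotted line is the floor of the normalized values at 4.41 scaled reads. Kit lies between 1.17 and 3.38 in the cultures labelled wild-type and between 1603 and 1738 in those labelled c-kitCre, while Xist shows the opposite order.

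Among 28 lists fixed beforehand, that of fibroblast and extracellular matrix genes had 20 of 38 members that rose, 2 that fell and 16 that did not pass (23 higher and 2 lower adjusted over the list alone). The list passed camera with its preset correlation (adjusted p = 2.3e-05) and did not with an estimated correlation (adjusted p = 0.309). Col1a2, a chain of type I collagen, rose from 3318 ± 343 to 78574 ± 16325 scaled reads, Col15a1 from 53.6 ± 21.5 to 2679 ± 117 and Thy1 as above, while Tnxb, a tenascin, fell from 1733 ± 62.3 to 179 ± 25.0 (SD, n = 3). Of 16 pericyte genes, 6 rose and 0 fell (6 higher and 0 lower adjusted over the list alone). These included Steap4, a metalloreductase, from 4.06 ± 1.92 to 733 ± 94.1, Anpep, an aminopeptidase, from 6.42 ± 5.86 to 481 ± 126, Ndufa4l2 from 35.7 ± 5.53 to 623 ± 231 and Mcam from 67.7 ± 32.0 to 417 ± 60.7. Camera gave an adjusted p = 0.0162, and 0.309 as adjusted p with an estimated correlation. Of 21 adipogenic and osteochondrogenic genes, 7 rose and 0 fell (7 higher and 0 lower adjusted over the list alone), among them the homeobox gene Msx1, from 0.80 ± 0.37 to 177 ± 39.7, Sox9, a regulator of cartilage formation, from 453 ± 63.8 to 1407 ± 145, and Pparg, the adipogenic nuclear receptor, from 3.29 ± 3.97 to 81.9 ± 24.5. Camera gave an adjusted p = 0.0182, and 0.383 as adjusted p with an estimated correlation. The call of this list was lost without c-kitCre culture 2 (adjusted p = 0.111).

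Of 31 genes of glycolysis and the response to hypoxia, 21 rose, 0 fell and 10 did not pass (23 higher and 0 lower adjusted over the list alone), in cultures that the labels all place at 21% oxygen. Camera gave an adjusted p = 8.94e-08 for the list, and 0.559 as adjusted p with an estimated correlation. Egln1, an oxygen-sensing prolyl hydroxylase, rose from 928 ± 259 to 9602 ± 282 scaled reads, Eno2, an enolase, from 8.28 ± 1.94 to 1296 ± 769 and Ankrd37, a target of hypoxia-inducible factor, from 70.1 ± 26.2 to 3045 ± 1648 (SD, n = 3). The mean of Eno2 in the cultures labelled c-kitCre is 855 without c-kitCre culture 2. In the Wnt list 17 of 38 genes rose and 5 fell (17 higher and 5 lower adjusted over the list alone). The Wnt inhibitors Sfrp1, above, and Notum, from 1.98 ± 1.66 to 119 ± 16.2, rose, as did the receptors Fzd6, from 3.65 ± 0.79 to 312 ± 119, and Lrp5, from 518 ± 4.73 to 4101 ± 912. Camera gave an adjusted p = 0.00219, and 0.309 as adjusted p with an estimated correlation. The estimate for the Wnt list, -0.0058, also lay below the preset 0.01.

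A further 3 lists passed camera. Of 36 interferon-stimulated genes, 14 rose and 3 fell (15 higher and 3 lower adjusted over the list alone). Ifih1, a sensor of viral RNA, rose from 1.70 ± 1.37 to 373 ± 112 scaled reads and Irf9 from 256 ± 12.5 to 646 ± 42.5, while Oas1a fell from 85.6 ± 61.8 (49.9 without wild-type culture 1) to 2.57 ± 1.96 (SD, n = 3). Its camera adjusted p = 0.0454 became 0.828 as adjusted p with an estimated correlation, 0.0501 on log2(scaled reads + 1) and 0.092 with centring on genes with a mean of at least 50. Its call was also lost when any culture except wild-type culture 1 was left out (adjusted p from 0.068, without c-kitCre culture 3, to 0.111, without c-kitCre culture 2). Of 41 cytosolic ribosomal protein genes, 5 rose and 0 fell (2 higher and 0 lower adjusted over the list alone), with Rpl13 from 2261 ± 165 to 5606 ± 1202. Its camera adjusted p = 0.0436 became 0.828 as adjusted p with an estimated correlation and 0.125 with median centring. Its call was also lost without wild-type culture 2 (adjusted p = 0.115), wild-type culture 3 (0.0985), c-kitCre culture 1 (0.0924) or c-kitCre culture 2 (0.188). Of 28 replication-dependent histone genes, 1 rose and 7 fell (1 higher and 6 lower adjusted over the list alone). Hist2h4 fell from 5318 ± 926 to 1262 ± 184, while the linker histone Hist1h1a rose from 23.4 ± 3.92 to 1977 ± 396. Histone genes have near-identical copies and their counts are uncertain. The camera adjusted p = 0.0162 became 0.828 as adjusted p with an estimated correlation, 0.0803 with median centring, 0.107 without wild-type culture 1 and 0.0993 without c-kitCre culture 3.

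**Figure D3:**
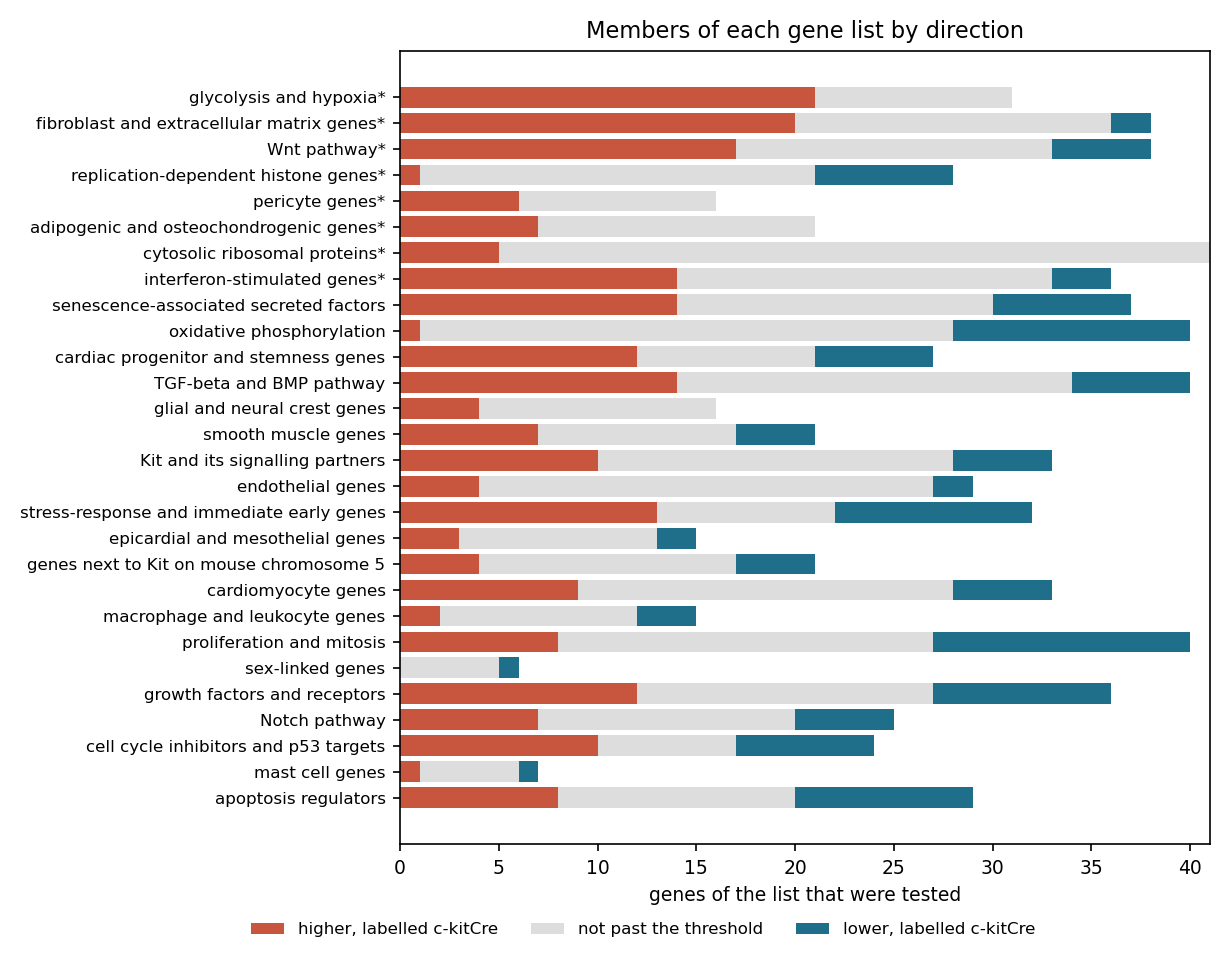
Number of genes tested in each of 28 lists (horizontal axis), split into members higher, not past the threshold and lower in the cultures labelled c-kitCre at an adjusted p under 0.05. Lists are ordered by their camera adjusted p and those marked with an asterisk passed it with the preset correlation, led by glycolysis and hypoxia with 21 members higher and 0 lower.

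The remaining 20 lists did not pass camera with the main settings. Under some other filter, scaling or pseudocount, or with a culture left out, 5 of them did: progenitor and stemness genes (smallest adjusted p = 0.0306), senescence-associated secreted factors (0.0128), oxidative phosphorylation (0.0197), Kit and its partners (0.0344) and the TGF-beta and BMP pathway (0.0344). In the list of Kit and its signalling partners, 10 of 33 genes rose and 5 fell (10 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.429). Stat3, a transcription factor activated by cytokine receptors, rose from 1267 ± 242 to 5555 ± 1119 scaled reads and the adaptor Gab2 from 230 ± 14.3 to 837 ± 44.0 (SD, n = 3). Of 21 genes next to Kit, 4 rose and 4 fell (4 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.604). They included Pdgfra, a receptor of cardiac mesenchymal cells, which rose from 580 ± 420 (337 without wild-type culture 1) to 8077 ± 945, and Ppat, which fell from 2143 ± 114 to 582 ± 56.7. Of 27 progenitor and stemness genes, 12 rose and 6 fell (12 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.0892). The heart transcription factors Hand2 and Tbx5 rose from 1.97 ± 1.19 to 339 ± 30.6 and from 6.50 ± 1.72 to 278 ± 42.9, and Ly6a, the gene of the Sca-1 antigen, fell from 3002 ± 272 to 729 ± 45.8. Of 33 cardiomyocyte genes, 9 rose and 5 fell (9 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.604), with the transcription factor Gata4 from 807 ± 25.9 to 2168 ± 179 and the connexin Gja1 from 1666 ± 292 to 12282 ± 3326. Of 21 smooth muscle genes, 7 rose and 4 fell (7 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.335). Tagln rose from 26.8 ± 4.72 to 815 ± 297 and Mylk, the myosin light chain kinase, fell from 1628 ± 605 to 67.4 ± 2.23.

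Markers of other cell types went both ways. Of 29 endothelial genes, 4 rose and 2 fell (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.439). Cdh5, the endothelial cadherin, measured 3.29 ± 0.72 and 12.8 ± 0.92 scaled reads in the cultures labelled wild-type and c-kitCre (SD, n = 3), and Eng, a TGF-beta co-receptor, fell from 2765 ± 598 to 471 ± 130. Only 15 macrophage and leukocyte genes and 7 mast cell genes passed the filter on low values. Of these 15, 2 rose and 3 fell (4 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.604), with Csf1r from 30.8 ± 7.55 to 141 ± 22.9 and Cd14 from 887 ± 415 to 129 ± 44.0. Of the 7 mast cell genes, Kit rose and Gata2 fell, from 1030 ± 108 to 411 ± 38.1 (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.892), and the mast cell proteases of the list lay below the filter. Of 16 glial and neural crest genes, 4 rose and 0 fell (4 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.335), with Gap43, a growth cone protein, from 3.41 ± 1.69 to 1105 ± 263 and Nes from 287 ± 148 to 1159 ± 253. Of 15 epicardial and mesothelial genes, 3 rose and 2 fell (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.604). Wt1, an epicardial transcription factor, rose from 8.40 ± 4.61 to 75.6 ± 4.85, against the fall of Msln.

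Cell cycle genes went both ways. In the proliferation list 8 of 40 genes rose and 13 fell (10 higher and 15 lower adjusted over the list alone; camera adjusted p = 0.615). The cyclin gene Ccnd1 fell from 25050 ± 3948 to 5921 ± 1471 scaled reads, Pcna, the DNA polymerase clamp, from 12373 ± 2119 to 4144 ± 573 and the replication helicase gene Mcm2 from 7408 ± 535 to 2240 ± 474 (SD, n = 3). Of 24 cell cycle inhibitors and p53 targets, 10 rose and 7 fell (10 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.767). Trp53 fell from 5542 ± 706 to 2487 ± 63.3 and the inhibitor Cdkn1b rose from 1714 ± 194 to 5698 ± 1398. Of 29 apoptosis regulators, 8 rose and 9 fell (9 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.957). Bid fell from 2334 ± 378 to 91.1 ± 27.6 and Apaf1, a part of the apoptosome, rose from 793 ± 66.9 to 2133 ± 292. Of 37 secreted factors tied to senescence, 14 rose and 7 fell (17 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.0673), with the cytokine Il6 from 2.44 ± 0.86 to 489 ± 34.8, Hgf from 9.45 ± 5.42 to 976 ± 358 and Igfbp4 from 18284 ± 3414 to 4104 ± 368.

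Among signalling and metabolic lists, 14 of 40 TGF-beta and BMP genes rose and 6 fell (14 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.117), with the BMP antagonist Grem1 from 3806 ± 88.1 to 14675 ± 363 scaled reads (SD, n = 3). Of 25 Notch genes, 7 rose and 5 fell (10 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.74), the ligand gene Jag1 falling from 2693 ± 330 to 112 ± 11.2. Of 36 growth factors and receptors, 12 rose and 9 fell (12 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.74). Igf1 rose from 12.9 ± 3.51 to 998 ± 139 and Egfr from 20.3 ± 2.87 to 861 ± 79.6, while Fgf7 fell from 6433 ± 831 to 117 ± 5.83. In the oxidative phosphorylation list 1 of 40 genes rose and 12 fell (1 higher and 12 lower adjusted over the list alone; camera adjusted p = 0.069), among them Cycs, the gene of cytochrome c, from 4169 ± 382 to 989 ± 273. Of 32 stress-response genes, 13 rose and 10 fell (14 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.481), with the early response gene Egr1 from 58.6 ± 9.99 to 1591 ± 181, and Trib3, a target of the amino acid response, from 8039 ± 674 to 778 ± 259. Of the 6 sex-linked genes only Xist passed (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.74). The Y-linked genes Ddx3y and Eif2s3y measured 1.52 ± 0.47 and 6.98 ± 1.22 in the cultures labelled wild-type, against 3.95 ± 2.70 and 19.2 ± 11.1 in those labelled c-kitCre.

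Median, mean and test went different ways in several of these lists. The apoptosis list had a median log2 difference of 0.07, a mean of 0.04 and a downward test. Negative means stood beside positive medians and upward tests for the epicardial list (-0.32 and 0.33) and the macrophage list (-0.01 and 0.42). The mast cell list (median -0.20, mean 0.92) and the growth factor list (median -0.05, mean 0.35) had upward tests, and the sex-linked list (median 0.16, mean -1.35) a downward one. The proliferation list had a median of 0 and a mean of -0.17.

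Cultures were also compared with one another across genes, which are not independent replicates. Pearson correlations of log2 values ranged from 0.895 to 0.927 between cultures of different labels. Within the cultures labelled wild-type they were 0.997 for cultures 2 and 3 and 0.983 and 0.982 for culture 1 with each. Within those labelled c-kitCre they were 0.993 for cultures 1 and 3 and 0.973 and 0.975 for culture 2 with each. Wild-type cultures 2 and 3 differed at least 2-fold in 314 genes. Over 1098 genes with a mean of at least 5000 scaled reads their log2 ratio had a robust SD of 0.06, against 0.02 estimated from counting alone and 0.41 and 0.43 for culture 1 with each. They were kept as the 2 cultures the labels name; library preparation also adds spread, so these values do not show that they were grown separately. With only 1 of them the genotype test called 5712 genes (without culture 2) or 6007 (without culture 3). With both kept and wild-type culture 1 left out it called 9047. The first principal component held 78.6% of the variance and separated the labels.

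The authors' deposited table of this comparison lists 4528 genes, 2225 higher in the cultures labelled wild-type and 2303 higher in those labelled c-kitCre. Every gene in it has a fold of at least 2.5 and a raw value of at least 35 in 1 or more cultures, and no other gene meets both limits. In the authors' deposited table Kit is 365-fold higher in the cultures labelled c-kitCre, Lama4 2685-fold and Cxcl12 1579-fold, while Xist is 763-fold higher in those labelled wild-type. Of the 4528 genes, 4127 (91.1%) also had an adjusted p under 0.05 in limma.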

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

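Alternatives added after the data were seen were the pseudocount of 1, scaling to the summed raw values, centring on genes with a mean of at least 50 and list tests under the scalings, pseudocounts and stricter filter. The count of 8578 genes stayed within 1.5 times under every filter, pseudocount and scaling (6892 to 11496), but the fallers numbered 8663 with median centring. Leaving out each culture gave 5712 to 9047 genes, 2505 to 4168 higher and 3207 to 4879 lower. Without wild-type culture 2 there were 5712 and 2505 higher, and without wild-type culture 3 2563 higher, with fewer samples in each of these fits. Without wild-type culture 1, with as many samples, there were 9047, so fewer samples alone do not account for the fall. The number of lists called, 8, became 0 with the estimated correlation and 19 with fry, which does not compare a list with other genes. The estimated correlation lay below the preset 0.01 for the pericyte and Wnt lists (-0.0261 and -0.0058). For the other called lists it ran from 0.0248 (adipogenic and osteochondrogenic) to 0.8174 (histone). A higher correlation therefore does not account for the loss of the pericyte and Wnt calls. With an estimated correlation camera also uses the 4 residual degrees of freedom of the fit, which it does not with a preset one. The loss of calls can thus not be assigned to correlation between genes, and these differences were not tested apart. The mean correlation between groups, 0.913, was 0.9388 without a filter and 0.8424 for a mean of at least 10, with other genes included.

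Ddx3y, not past the threshold, was -0.1351 with median centring and ran from 0 (without c-kitCre replicate 2) to 0.328 with a culture left out. Lists that did not pass camera turned direction in it, with these adjusted p-values (fry called 3 of them, mast cell at 4.49e-05, growth factors at 0.000772 and sex-linked at 0.0238): apoptosis 0.881 (mean of at least 10), 0.52 (quantile), 0.721 (median centring), 0.792 (without wild-type replicate 1) and 0.971 (without c-kitCre replicate 3; range with a culture left out 0.78 to 0.971); mast cell 0.931 (mean of at least 10) and 0.996 (centring at 50, also cell cycle inhibitors and growth factors); proliferation 0.677 (quantile) and 0.826 (without wild-type replicate 1; range 0.398 to 0.826); sex-linked 0.9 (without c-kitCre replicate 1; range 0.647 to 0.9). The cause was not tested. For the 125 named genes, 1238 of 1246 values under other settings and 733 of 750 with a culture left out kept direction and side of the threshold; the calls lost were of Rps19, Rpl22, Hist1h1b and Hist2h2ac. Calls gained were of Eif2s3y (adjusted p = 0.0334 with centring at 50, 0.0351 without c-kitCre replicate 1, 0.0486 without c-kitCre replicate 2) and Tph1 (0.0245 without c-kitCre replicate 3). Camera also called oxidative phosphorylation with no filter (adjusted p = 0.0197), median centring (0.0443), summed raw values (0.0406) and without wild-type replicate 2 (0.0289), wild-type replicate 3 (0.0242) or c-kitCre replicate 2 (0.0328). It called the senescence list with no filter (0.0195), a pseudocount of 0.1 (0.048), quantile normalization (0.0461), median centring (0.0136) and without wild-type replicate 1 (0.0128), progenitor genes with no filter (0.0442), quantile normalization (0.0344) and median centring (0.0306), and the Kit partner and TGF-beta lists with quantile normalization (0.0344 each).

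The replicate block gave 8212 genes (3746 higher, 4466 lower) and ended the interferon call (adjusted p = 0.0517) and that of Rps19, and Eif2s3y passed (adjusted p = 0.0463). Same-numbered cultures had correlations of deviations of 0.082, -0.021 and 0.186, so the numbers were not taken as pairs. Not run, because the values are 1 per culture and not counts: TMM, DESeq2 size factors, upper-quartile factors, DESeq2, voom, single-library and duplicateCorrelation fits and the test among cultures; the authors' table holds no p for its thresholds.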

Other observations

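The imprinted and Hox gene lists, the off/on limits and all tests of this part except that of GC content and length were chosen after the values were seen. Several imprinted genes, expressed from 1 parental copy, were low in the cultures labelled wild-type and on in those labelled c-kitCre. Meg3 reached 1832 ± 425 scaled reads, Peg3 561 ± 112, Plagl1 538 ± 378, H19 207 ± 136 and Dlk1 191 ± 74.3 (SD, n = 3), with log2 differences between 5.30 and 6.88 (limma, adjusted p from 6.37e-05 to 0.000504). Without c-kitCre culture 2 the means of Plagl1 and H19 were 319.9 and 129. Near the floor, the mean of Peg3 in the cultures labelled wild-type, 3.95, was 2.47 without wild-type culture 1, and that of H19, 1.89, was 1.18 without wild-type culture 3. Of 30 imprinted genes tested, 12 rose and 3 fell, where 35.5% of all genes tested passed. The fallers were Impact (log2 difference -1.37, adjusted p = 0.00194), Asb4 (-1.59, adjusted p = 0.00347) and Blcap (-0.98, adjusted p = 0.00686). Igf2 (-0.93, adjusted p = 0.173), Snrpn (-0.17, adjusted p = 0.547) and Mest (0.00, adjusted p = 0.999) were among those that did not pass.

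Hox genes, which record position along the body axis, went both ways: of 32 tested, 8 rose and 4 fell. That share is near the 35.5% of all genes tested that passed, and no list test was run on the imprinted and Hox lists. Hoxd8 and Hoxa10 reached 156 ± 17.7 and 142 ± 23.1 scaled reads in the cultures labelled c-kitCre (log2 differences 5.03 and 4.78; limma, adjusted p = 0.000133 and 0.000162), while Hoxb13, Hoxa2 and Hoxa6 fell (log2 differences -2.88, -2.22 and -2.11; adjusted p = 0.00169, 0.006 and 0.00849). Hoxb4 (-0.01) and Hoxa5 (-0.14) did not pass.

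Kit was one of 143 genes under 10 scaled reads in all cultures of one group and over 200 in all of the other, 122 of them on in the cultures labelled c-kitCre and 21 in those labelled wild-type. Of these genes, 133 lie on other chromosomes than 5, 9 on chromosome 5 and 1 has no chromosome in the annotation; this does not decide whether some follow from the difference in Kit. An exchange of the labels of both groups cannot be told apart from the labels as given: Kit in the cultures labelled wild-type was 0.1202% of that in the others, and no table holds the genotype. Kit is also the gene that raised this question, so its level is no independent test of an exchange. Whether exchanged labels would account for a difference of 832-fold was not tested. A difference in the origin or state of the cells, confounded with the genotype, stays open and untested.

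Chromosomes differed in their median shift between the groups. Relative to all genes, median log2 differences ran from -0.51 on chromosome 15 to 0.63 on chromosome 8, while cultures within a group differed by at most 0.12. For 18 of 20 chromosomes all 9 pairs of cultures across the groups had one sign, where exchangeable cultures would give 10%. With 35.5% of genes different between the groups, large sets of genes picked without regard to chromosome could also give one sign. This count therefore does not by itself show shifts by chromosome. Blocks of 20 neighbouring genes regulated together are argued against: the SD of chromosome medians, 0.34, was reached in none of 1000 shuffles of such blocks (largest 0.16; permutation p = 0.001, the smallest they can give). Removing the trends with GC content and gene length left that SD at 0.3374. Different chromosome copy numbers remain a candidate explanation: the medians of the first and second part of each chromosome went together (Pearson r = 0.797, permutation p = 3e-05; Spearman rho = 0.768, p = 0.00018; r = 0.743 without chromosomes 8 and 18), though the parts had opposite signs on 4 chromosomes (4, 5, 11 and 17), and regulation over whole chromosomes and the genotype itself were not tested apart from it.

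Xist fell to 48.4 ± 17.5 scaled reads in the cultures labelled c-kitCre. Cells with a transcribed Y chromosome are argued against, since Ddx3y stood at 0.05014% of its X-linked partner Ddx3x there. The Y-linked Kdm5d measured 79.2 ± 33.8 and 51.2 ± 17.9 scaled reads in the cultures labelled wild-type and c-kitCre (SD, n = 3), above the floor of 4.41. Its X-linked partner Kdm5c measured 3689 ± 67.2 and 6207 ± 1064. Whether the reads counted for Kdm5d came from a Y chromosome was not tested. A Y chromosome lost in culture was not tested. A pair of active X chromosomes cannot be told apart from other changes: X-linked genes lay 0.5699 above autosomal genes in median log2 difference, but chromosome 8 was shifted as far. Of 4 genes known to escape inactivation, Ddx3x and Eif2s3x fell by 1.34 and 0.89 on the log2 scale, Kdm5c rose by 0.74 and Kdm6a (-0.26, adjusted p = 0.172) did not pass (limma).

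The real split of the 6 cultures gave 8578 genes, and the highest of the other splits gave 0. Each other split mixes both labels within its groups, so the large difference between the labels enters the spread within groups. A count near 0 was thus set in advance there, and no conclusion is drawn from it. Only 1 of the 10 splits, the real one, gave 8578 genes, and 10 splits are too few for a share under 0.05.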
